A study of Escherichia coli with 15 samples.

How the data were processed

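The series holds 15 one-colour Affymetrix E. coli Antisense Genome arrays of MG1655, 1 per sample, with total RNA reverse-transcribed and labelled. Per the labels, cells were sampled at mid-log phase from aerobic cultures in MOPS minimal medium with 1 of 6 carbon sources: 5 arrays for glucose, and 2 each for acetate, glycerol, succinate and the L-forms of alanine and proline. Groups and replicate numbers were read from the sample titles. Growth rates were not given.

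The deposited values are signal intensities on a linear scale, 1 per probe set, for 7312 probe sets. The software that made them is not given in the sources used here. In the values, the 2% trimmed mean of every array lay at 1000.4 to 1000.6, so the deposited scale was kept, while medians and sums differed between arrays. There were 17 values of exactly 0 and no missing ones, and 0 columns lacked a sample. The probe sets comprised 4345 for genes, 2886 intergenic, 59 for phage or plasmid sequences and 22 Affymetrix controls. Gene names were taken by b number from the reference annotation of MG1655: 4183 probe sets by their b number, 113 by a former one, and 49 were not found and kept the name on the array. The platform's annotation gave 1 symbol for 3656 gene probe sets, several for 589 and none for 100 that it did not list. The names of 126 probe sets mark them as able to bind more than 1 sequence, and 54 symbols had several probe sets (114 in all), of which the one with the highest mean was named.

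Values were floored at 15.1, the 5th percentile of all values, which held 1.85% of gene values, and taken to log2. A linear model of the 6 group means was fitted to the 4345 gene probe sets over all 15 arrays in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with moderated variances that follow the mean signal. There were 9 residual degrees of freedom per gene and a median of 13.5 in total. Every adjusted p of a gene is that of the two-sided limma moderated test with the Benjamini-Hochberg correction within the comparison, and genes under 0.05 were called. Each source was compared with glucose and with the mean of the other 4 non-glucose sources. An F-test covered all 6 groups, and a linear contrast over the 5 sources in their listed order was set against all 60 orders that differ by more than reversal. The overlap of the 5 comparisons was set beside independent lists. For pairs of sources the correlation of changes was set beside 50 simulations of unchanged groups sharing the glucose arrays and beside estimates with the glucose arrays divided 3 and 2. In the simulations at most 2 genes were called per comparison, too few to test the overlap of calls.

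In 30 lists of genes of known function, written from general knowledge, members called higher and lower were counted, also with the correction made over the list alone. Lists of at least 3 members (29) were tested with camera at a preset correlation of 0.01, corrected over all lists and comparisons, and again with a correlation estimated for each list. The genes named are the 8 largest rises and 6 largest falls per comparison with glucose, among called genes whose arrays do not overlap with those of glucose. Up to 4 called members of each list, all members of the 5 substrate lists, crp, cyaA and ptsG could be named too. So could the 5 largest rises of each source over the other sources, the 5 steepest slopes each way, and the 5 genes each way with the largest smallest change common to the 5 sources. The comparisons, the tests named so far, the lists, the naming rule and all alternatives but 1 were chosen before the data were examined. Further tests chosen after a result was seen are marked where they are given.

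The alternatives were quantile normalization, arrays centred on their median, a floor at the 20th percentile (72.6), no floor, an added 31.5 (10th percentile) in place of a floor, dim probe sets left out, a minimum change of 2-fold, robust moderation, no variance trend, arrays of the compared groups alone, the replicate number as a block, probe sets of a gene averaged, and each array left out in turn. For lists they were camera with an estimated correlation, fry and quantile normalization. A fit without the 3 arrays least like their groups was added after the arrays were compared.

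The steps were tested on simulated values without group differences, drawn independently for each gene rather than taken from the real arrays. In each of 20 draws 200 of 4345 genes were changed. Variation shared by the genes of an array was not simulated, so the shares that follow leave it out. For proline against glucose 44.2% of changes of log2 1 and 82.7% of changes of log2 2 were recovered, 0 with the wrong sign, and 5.05% of calls were false on average (1.50% to 8.67% per draw). Slopes of 0.5 per step were recovered for 82.0 of 100 genes. A changed list was called in 20 of 20 draws, with 0.05 other lists called on average. Since the simulated genes were independent, these draws do not measure false calls of lists whose genes vary together. In the real data the estimated correlation was 0.44 for the ribosomal protein genes, for example. Intergenic, phage and plasmid and control probe sets were left out of the comparisons of genes and are treated separately.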

Results

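RNA of Escherichia coli MG1655, a K-12 strain, was measured on 15 one-colour Affymetrix antisense genome arrays. The cells grew aerobically to mid-log phase in MOPS minimal medium with one carbon source. There were 5 arrays for glucose and 2 each for glycerol, succinate, alanine, acetate and proline, and this number limits the precision. The summed signal per array ran from 9815038 to 13720983.6 and the array median from 246.1 to 390.1. Phage and plasmid probe sets, whose sequences MG1655 lacks for the most part, served as a background reference, and their 95th percentile was 299.4 to 598.9 per array. Glucose replicates 3 and 5 had mean correlations with their group of 0.934 and 0.927, and the pair of succinate arrays correlated at 0.936, where other groups and arrays reached at least 0.943. The 1 correlation of the succinate pair does not show which of its arrays differs. Succinate replicate 2 had the highest background reference. The 100 brightest gene probe sets held 26.8% to 35.4% of the summed signal on the glucose arrays and 19.8% to 26.5% on the other 10. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples.

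The sources drew apart from glucose to different degrees. Among 4345 genes, 225 were higher and 108 lower on glycerol than on glucose, and 194 and 102 on succinate. On alanine 546 were higher and 312 lower, on acetate 713 and 462, and on proline 713 and 558. Changes of at least 2-fold were found for 127 and 37 genes on glycerol, 122 and 30 on succinate, 374 and 158 on alanine, 481 and 211 on acetate, and 498 and 281 on proline. At an unadjusted p under 0.05 the counts were 954, 919, 1352, 1607 and 1683. In the limma F-test 1073 genes differed among the 6 sources. The median log2 change of all genes was 0.07, 0.11, 0.22, 0.17 and 0.14 on the 5 sources with the deposited scale and -0.01, -0.01, -0.02, -0.04 and -0.07 after quantile normalization. Medians of gene lists are therefore given less that of all genes. The median standard error of a log2 change was 0.30. Where a source is compared with the other 4 sources, the contrast is with the mean of those 4, so a gene called higher there can be as high or higher on 1 of them.

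**Figure D1:**
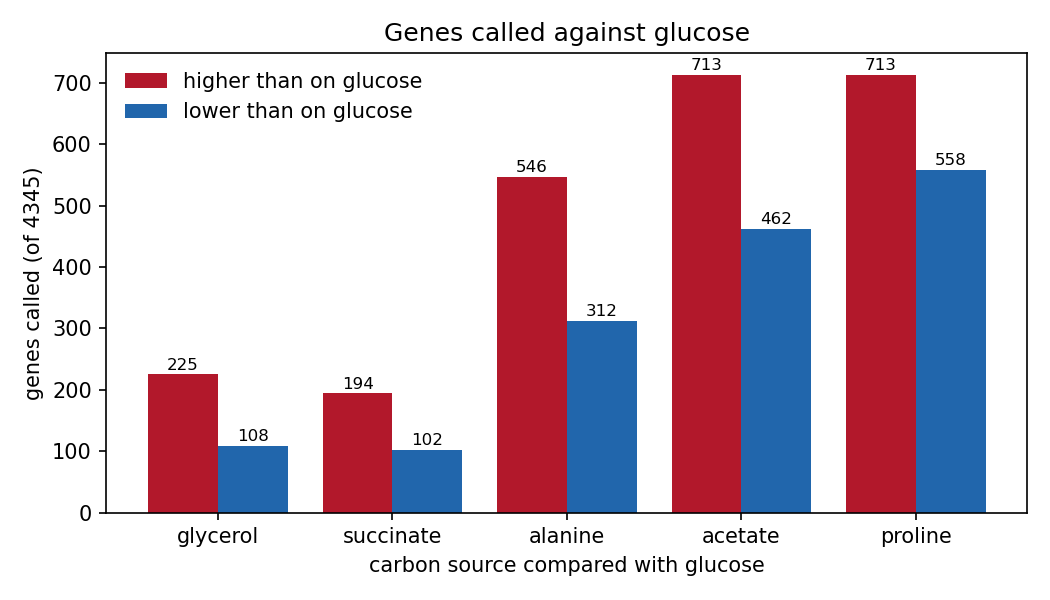
Number of genes called higher (red) or lower (blue) on each carbon source than on glucose, of 4345 genes tested with limma. The counts are lowest on succinate (194 and 102). The count of lower genes is highest on proline (558), and the count of higher genes is highest on acetate and proline (713 each).

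Glycerol, taken up through a facilitator and phosphorylated by glycerol kinase, was compared with glucose to ask which genes change when it is the carbon source. Its own uptake and oxidation genes rose. The kinase gene glpK rose by 2.83 ± 0.30 (log2 change ± SE, n = 2 against 5, adjusted p = 5.31e-05). So did glpF, the facilitator, by 2.59 ± 0.24 (adjusted p = 1.71e-05), and glpQ, a periplasmic phosphodiesterase, by 3.11 ± 0.26 (adjusted p = 5.26e-06). Of the 8 members 7 rose (7 adjusted over the list alone; camera adjusted p = 6.85e-13; adjusted p = 0.0379 with an estimated correlation). The gene not called was glpD, the aerobic glycerol 3-phosphate dehydrogenase (0.30 ± 0.21, adjusted p = 0.451). Other large rises were those of tnaC, the leader peptide of the tryptophanase operon (4.74 ± 0.27), yjcH, which lies between acs and actP (4.47 ± 0.45), and mglB and mglA of the galactose ABC transporter (3.03 ± 0.14 and 2.94 ± 0.34). Others were those of gpr (3.01 ± 0.64), curA (3.02 ± 0.59) and patD, an aminobutyraldehyde dehydrogenase (2.87 ± 0.63). The largest falls were those of amtB, the ammonium channel (-3.63 ± 0.67), glnK, its partner PII protein (-3.37 ± 0.57), and mqo, malate:quinone oxidoreductase (-2.90 ± 0.24). Next came ptsG, the glucose permease (-2.72 ± 0.13), the curli gene csgF (-2.59 ± 0.38) and yjfZ (-2.59 ± 0.58).

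Against the mean of the other 4 sources limma called 0 of the 8 glycerol genes higher or lower on glycerol, with 4 at an unadjusted p under 0.05, and glpK stood at -0.43 ± 0.28 (adjusted p = 0.581). In that contrast 38 genes were higher and 115 lower. The rises were led by the small RNA gene spf (1.83 ± 0.31, adjusted p = 0.00460), uraA, the uracil permease (1.78 ± 0.23), gpmM, a phosphoglycerate mutase (1.38 ± 0.20), ftnA, a ferritin (1.29 ± 0.26), and stpA, a paralogue of H-NS (1.26 ± 0.19). The mean levels of spf and uraA on succinate were not below those on glycerol (-2.41 and -0.28 against glucose, and -2.46 and -0.73 on glycerol). Without glycerol replicate 1 the counts against glucose were 86 and 24 and against the other sources 7 and 39. Without replicate 2 they were 103 and 34, and 3 and 16. Without replicate 1 the calls of curA (adjusted p = 0.154), glnK (0.0748) and stpA (0.0538) ended. Without replicate 2 those of amtB (0.0773), spf (0.20), uraA (0.0513) and gpmM (0.0655) did (adjusted p). Leaving out either replicate 1 or 2 ended those of gpr (0.105 and 0.0981), patD (0.157 and 0.0745), yjfZ (0.150 and 0.0960) and ftnA (0.124 and 0.233). With arrays centred on the median the counts against glucose were 132 higher and 129 lower.

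Succinate, a C4-dicarboxylate that enters aerobic cells through DctA, was compared with glucose in the same way. The carrier gene dctA rose by 3.61 ± 0.17 (adjusted p = 1.81e-08), from a signal of 554 ± 106 (SD, n = 5) on glucose to 6674 ± 427 (SD, n = 2). It was also higher on succinate than the mean of the other 4 sources, by 1.20 ± 0.16 (adjusted p = 0.000514). It was called higher on every one of the 5 sources, with changes of 1.76, 3.61, 2.45, 2.74 and 2.71 in the order glycerol, succinate, alanine, acetate, proline. The sensor kinase gene dcuS rose as well (1.07 ± 0.22). In all, 2 of the 7 C4-dicarboxylate uptake genes rose (3 adjusted over the list alone; camera adjusted p = 0.0116; adjusted p = 0.0769 with an estimated correlation). The regulator gene dcuR and the carriers dcuA, dcuB, dcuC and dcuD stood at 1.86, 0.25, -0.84, 0.22 and 0.48 without a call. Large rises were further those of yjcH (4.27 ± 0.45), tnaC (4.14 ± 0.27), gpr (3.10 ± 0.64), yagE (2.91 ± 0.43), mglA (2.90 ± 0.34), mglB (2.85 ± 0.14) and acs, acetyl-CoA synthetase (2.68 ± 0.20). Large falls were those of amtB (-3.58 ± 0.67), ptsG (-2.84 ± 0.13), spf (-2.41 ± 0.33), the curli gene csgE (-2.38 ± 0.52), glnK (-2.34 ± 0.57) and yagU (-2.26 ± 0.44).

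On succinate 56 genes were higher and 178 lower than the mean of the other 4 sources. The rises were led by uraA (2.34 ± 0.23, adjusted p = 8.28e-05), mqo (2.14 ± 0.23), spf (1.89 ± 0.31), the recombinase gene fimB (1.58 ± 0.42) and pyrB, a subunit of aspartate carbamoyltransferase (1.52 ± 0.18). Without succinate replicate 1 the counts were 119 and 83 against glucose and 22 and 152 against the other sources. Without replicate 2 they were 127 and 39, and 22 and 63. Without proline replicate 2 the second pair was 34 and 146. Without replicate 1 the calls of amtB (adjusted p = 0.0609), csgE (0.0811), glnK (0.223), gpr (0.0699) and fimB (0.0914) ended. Without replicate 2 those of csgE (adjusted p = 0.0855), gpr (0.0756), yagU (0.0817), spf against the other sources (0.0892) and fimB (0.356) ended. The call of fimB also ended without any one of 10 other arrays (adjusted p = 0.0501 to 0.0852), the exceptions being glucose replicate 5 and the pair of alanine arrays. With arrays centred on the median 118 genes were higher and 99 lower than on glucose. Fewer genes were called either way in the fit without the 3 arrays least like their groups, which leaves 1 succinate array.

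Alanine is imported by CycA, converted between its L- and D-forms by the racemase DadX and oxidised by the dehydrogenase DadA. All 3 genes of this list rose on alanine (3 adjusted over the list alone; camera adjusted p = 7.05e-06; adjusted p = 0.0379 with an estimated correlation). The rise of dadA was 4.40 ± 0.21 (adjusted p = 1.60e-08), that of dadX 4.20 ± 0.37 and that of cycA 1.65 ± 0.15. The signal of dadA was 708 ± 161 on glucose and 14691 ± 1113 on alanine (SD, n = 5 and 2). The 3 genes were higher than the mean of the other 4 sources too, by 2.69 ± 0.20, 2.83 ± 0.35 and 1.28 ± 0.14 (adjusted p = 6.51e-06, 0.000737 and 0.000245). The gene alaE, an alanine exporter, rose by 7.11 ± 0.58 (adjusted p = 1.96e-06), from a signal of 34.3 ± 28.5, below background, to 4014 ± 93.4. This fold depends on the floor, and with a floor of 72.6 it was 5.75, with yjcH at 5.79. On the other sources alaE was not called. Large rises were also those of yjcH (5.92 ± 0.45), curA (4.87 ± 0.59), tnaC (4.64 ± 0.27), patD (4.22 ± 0.63) and ydcS, a periplasmic binding protein (4.10 ± 0.74). The largest falls were those of spf (-4.42 ± 0.33), stpA (-3.65 ± 0.20), livJ, the leucine and isoleucine binding protein (-2.54 ± 0.25), the serine tRNA gene serT (-2.52 ± 0.51), drpB (-2.51 ± 0.51) and yagU (-2.38 ± 0.44).

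On alanine 28 genes were higher and 12 lower than the mean of the other 4 sources. The rises were led by alaE (5.89 ± 0.55), csgE (2.87 ± 0.49), dadX, dadA and eco, the periplasmic protease inhibitor ecotin (2.25 ± 0.17, adjusted p = 7.84e-06). Without alanine replicate 1 the counts were 275 and 168 against glucose and 9 and 5 against the other sources. The call of drpB ended (adjusted p = 0.102). Without replicate 2 they were 278 and 119, and 9 and 3, and the calls of serT (adjusted p = 0.101) and of csgE (0.436) ended. With arrays centred on the median 318 genes were higher and 508 lower than on glucose.

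Acetate is activated by acetyl-CoA synthetase (acs) and fed through the glyoxylate shunt, whose enzymes are isocitrate lyase (aceA) and malate synthase (aceB). All 6 genes of this list rose on acetate (6 adjusted over the list alone; camera adjusted p = 6.66e-09; adjusted p = 0.0379 with an estimated correlation). The change of yjcH was 6.42 ± 0.45, of the permease gene actP 4.26 ± 0.15, of acs 4.26 ± 0.20 (adjusted p = 7.10e-09) and of aceA 2.66 ± 0.20. The signal of acs was 614 ± 76.1 on glucose, 11881 ± 3029 on acetate and 12432 ± 1519.6 on proline. On acetate acs, actP and aceK, the isocitrate dehydrogenase kinase, were higher than the mean of the other 4 sources by 0.96, 0.98 and 0.83 (adjusted p = 0.0138, 0.00161 and 0.0171). Their mean levels on proline were not below those on acetate, with changes against glucose of 4.34, 4.29 and 1.88 on proline and 4.26, 4.26 and 1.87 on acetate. In the same contrast aceA (0.63 ± 0.19, adjusted p = 0.120) was not called. Large rises against glucose were also those of tnaC (5.81 ± 0.27), ydcS (5.56 ± 0.74), curA (5.49 ± 0.59), patD (5.29 ± 0.63), ydcV (4.77 ± 0.46), mocA (4.71 ± 0.46) and glcD, a subunit of glycolate oxidase (4.62 ± 0.54). Large falls were those of spf (-5.37 ± 0.33), uraA (-4.14 ± 0.24), yagU (-3.14 ± 0.44), gltF (-2.75 ± 0.47), pyrB (-2.75 ± 0.19) and glnK (-2.75 ± 0.57).

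On acetate 84 genes were higher and 32 lower than the mean of the other 4 sources. The rises were led by yhjY (2.22 ± 0.55, adjusted p = 0.0480), mcbR, a biofilm regulator (2.10 ± 0.31), glcD (2.08 ± 0.51) and sgcQ and sgcX (2.04 ± 0.48 and 1.89 ± 0.46). Of these mcbR, sgcQ and sgcX had higher means on proline, a difference that was not tested, with changes against glucose of 4.59, 4.36 and 4.67 there and 4.07, 3.82 and 4.53 on acetate. Without acetate replicate 1 the counts were 412 and 269 against glucose and 6 and 6 against the other sources. Without replicate 2 they were 443 and 236, and 33 and 8. Without alanine replicate 1 the second pair was 53 and 19, and without glycerol replicate 2 it was 60 and 21. The calls of yhjY, glcD, sgcQ and sgcX against the other sources ended without acetate replicate 1 (adjusted p = 0.511, 0.493, 0.380 and 0.441). They ended also without replicate 2 (adjusted p = 0.267, 0.305, 0.360 and 0.364) and without most other single arrays (0.0512 to 0.101). That of mcbR ended without acetate replicate 1 (adjusted p = 0.0773). With arrays centred on the median 460 genes were higher and 722 lower than on glucose.

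Proline is imported by PutP and oxidised to glutamate by PutA. Both genes rose on proline, putP by 3.17 ± 0.20 (adjusted p = 1.56e-07) and putA by 3.35 ± 0.43 (adjusted p = 5.15e-05). The signal of putP went from 1216 ± 228 on glucose to 10791 ± 326 (SD, n = 5 and 2). Relative to the mean of the other 4 sources they were higher by 2.81 ± 0.19 and 2.78 ± 0.41 (adjusted p = 5.01e-06 and 0.00133); putP was also higher than on glucose on acetate (1.12 ± 0.20). Of these 2 genes 0, 0, 0, 1 and 2 were called higher on glycerol, succinate, alanine, acetate and proline (0, 0, 1, 1 and 2 adjusted over the list alone), with 0, 0, 1, 1 and 2 at an unadjusted p under 0.05. The glutamate decarboxylase gene gadA rose by 5.75 ± 0.64 against glucose and by 4.74 ± 0.61 against the other sources. In the latter contrast the regulator gene gadE (4.51 ± 0.77), gadB (4.26 ± 0.64), the acid chaperone gene hdeB (3.61 ± 0.41) and bssR (3.30 ± 0.58) followed. Large rises against glucose were further those of yjcH (6.65 ± 0.45), tnaC (6.31 ± 0.27), ydcS (5.60 ± 0.74), curA (5.49 ± 0.59), patD (5.11 ± 0.63), mocA (4.84 ± 0.46) and bssR (4.72 ± 0.61). Large falls were those of spf (-4.95 ± 0.33), glnK (-4.02 ± 0.57), fimB (-3.76 ± 0.45), yhcN (-3.56 ± 0.47), uraA (-3.48 ± 0.24) and the prepilin peptidase gene pppA (-3.46 ± 0.30).

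Against the mean of the other 4 sources 143 genes were higher and 113 lower on proline. Without proline replicate 1 the counts were 404 and 365 against glucose and 38 and 30 against the other sources. Without replicate 2 they were 454 and 342, and 39 and 16. The calls of gadE (adjusted p = 0.0747 and 0.0592) and bssR (0.0767 and 0.0749) against the other sources ended each time. The balance of higher and lower genes against glucose turned with the scaling. After quantile normalization 581 genes were higher and 729 lower than on glucose, and 155 higher and 205 lower than on the other sources. With arrays centred on the median the counts were 471 and 864 against glucose and 107 and 96 against the other sources, where the balance turned only after quantile normalization.

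**Figure D2:**
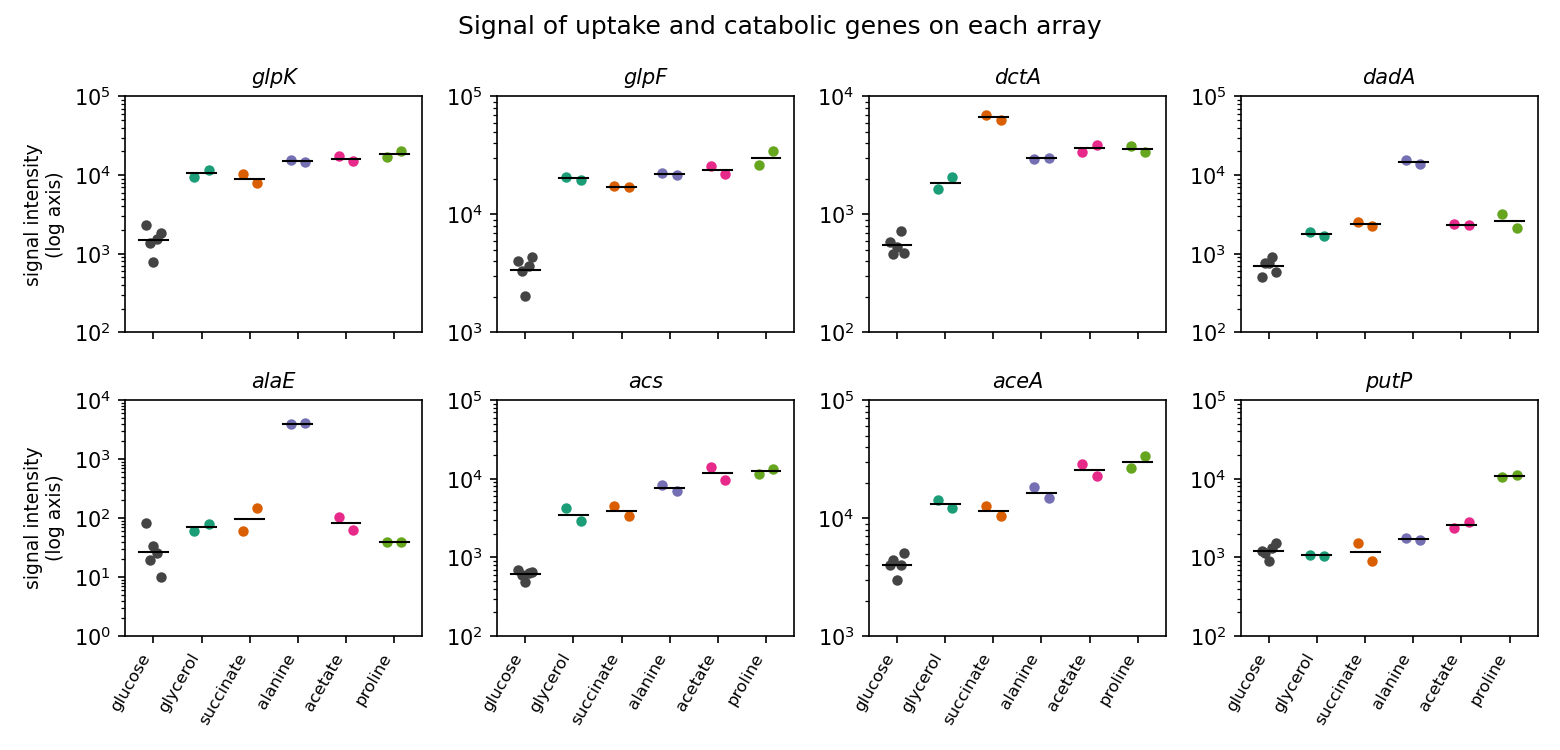
Signal intensity (log axis) on each array of genes for glycerol (glpK, glpF), succinate (dctA), alanine (dadA, alaE), acetate (acs, aceA) and proline (putP), by carbon source; points are arrays and lines geometric means. The glycerol genes are raised on all 5 sources, and dctA, dadA and putP are highest on their own substrates.

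Many changes were shared by the 5 sources. In all 5 comparisons with glucose 132 genes were higher and 44 lower. Independent lists of these sizes give 0.0340 and 0.00249, values that leave out the sharing of the glucose arrays, and how much that sharing adds to the counts was not measured. The genes with the largest smallest rise were yjcH, tnaC, gpr, mglA and mglB, with changes of 4.47, 4.27, 5.92, 6.42 and 6.65 for yjcH and 3.03, 2.85, 3.10, 3.10 and 2.66 for mglB in the order glycerol, succinate, alanine, acetate, proline. Those with the largest smallest fall were spf (-2.46, -2.41, -4.42, -5.37 and -4.95), ptsG (-2.72, -2.84, -2.30, -2.09 and -2.43), yagU, glnK and gltF. The regulator genes crp and cyaA, which act in the response to glucose, were not called on any source (crp -0.27 to -0.37, cyaA -0.34 to -0.11 on glycerol and proline). Across genes, the changes on pairs of sources correlated at r = 0.607 to 0.869, and at mean r = 0.441 to 0.741 when the glucose arrays were divided between the members of the pair. Simulated unchanged groups with shared glucose arrays gave 0.284, and genes are not independent replicates. Acetate and proline shared 576 higher and 378 lower genes (117 and 59.3 from independent lists). Without glycerol replicates 1 and 2 in turn, 75 and 84 genes were higher on all 5 sources and 9 and 16 lower. The lower count was 24 and 27 without succinate replicates 1 and 2 and 24 without either alanine replicate.

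Members of uptake and catabolic lists for substrates other than the one supplied rose on the 5 sources. The counts that follow are in the order glycerol, succinate, alanine, acetate, proline, with those adjusted over the list alone in parentheses. Of the 8 glycerol genes 7, 7, 8, 8 and 8 rose (7, 8, 8, 8 and 8 adjusted over the list alone), and of the 6 acetate and glyoxylate genes 6, 4, 6, 6 and 6 (6, 6, 6, 6 and 6 adjusted over the list alone). Camera called both lists up everywhere, at adjusted p = 0.0379 with an estimated correlation. Of the 8 fatty acid oxidation genes 4, 4, 8, 8 and 8 rose (7, 5, 8, 8 and 8 adjusted over the list alone), among them fadB (1.44, 1.38, 2.38, 2.58 and 2.54) and the transporter gene fadL (0.99, 0.79, 2.22, 2.47 and 2.35). That list too was called up everywhere, at adjusted p = 0.0379 with an estimated correlation. The 3 alanine genes rose in 1, 1, 3, 3 and 3 (2, 2, 3, 3 and 3 adjusted over the list alone) and the 7 C4-dicarboxylate genes in 2, 2, 5, 4 and 3, with dcuB lower on acetate (-1.43 ± 0.47), and 4, 3, 5, 4 and 3 were higher adjusted over the list alone. After quantile normalization 2, 2, 2, 4 and 3 of those 7 were higher and 0, 0, 1, 1 and 1 lower. Apart from alanine itself, camera calls of the first had adjusted p = 0.114 to 0.142 with an estimated correlation. The second had adjusted p = 0.0769 to 0.142 with an estimated correlation and was not called on proline by either form. Of 11 maltose genes 5, 6, 7, 7 and 7 rose (6, 6, 7, 7 and 7 adjusted over the list alone), with malK at 1.64, 1.93, 2.72, 2.51 and 2.59, and 1 fell on proline. Of 9 galactose genes 4, 4, 3, 6 and 7 rose (6, 8, 5, 7 and 7 adjusted over the list alone), while the permease gene galP fell on glycerol, acetate and proline (-2.59, -1.87 and -3.08), and with quantile normalization 1, 0, 1, 1 and 1 members fell. Of 6 ribose genes 3, 3, 4, 5 and 5 rose (5, 4, 5, 5 and 5 adjusted over the list alone), with rbsB at 1.23, 1.10, 1.36, 1.39 and 1.41 from a probe set that may bind other sequences. Of 44 genes for other sugars and sugar alcohols 9, 9, 19, 23 and 24 rose (16, 13, 22, 28 and 24 adjusted over the list alone), with the galactitol gene gatD at 2.71, 2.62, 3.06, 3.61 and 3.39 and the trehalose permease gene treB at 2.76, 2.35, 2.92, 3.18 and 2.97. Camera called these lists up on every source, and each call was lost with the other form, at adjusted p = 0.0915 to 0.142 (maltose), 0.0919 to 0.20 (galactose), 0.0536 to 0.119 (ribose) and 0.0527 to 0.0641 (other sugars) with an estimated correlation. Fewer maltose genes rose on succinate without the 3 arrays least like their groups, a fit that leaves 1 succinate array.

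Amino acid catabolism rose in 5, 4, 12, 12 and 12 of 23 genes (7, 7, 14, 12 and 14 adjusted over the list alone), led by the tryptophanase gene tnaA (2.82, 2.61, 2.88, 3.91 and 3.92), and on acetate and proline 2 and 1 fell. After quantile normalization 3, 2, 11, 11 and 10 rose and 0, 0, 0, 2 and 2 fell. Camera called it up on every source, at adjusted p = 0.10, 0.0743, 0.0379, 0.10 and 0.0915 with an estimated correlation. Of 30 peptide and amino acid ABC transport genes 6, 6, 11, 7 and 9 rose (8, 6, 15, 8 and 10 adjusted over the list alone) and 1, 1, 3, 3 and 3 fell (1, 2, 4, 3 and 4 adjusted over the list alone). Among them the dipeptide binding protein gene dppA rose by 1.34, 1.37, 1.70, 1.44 and 1.58. On glycerol, succinate and alanine camera called the list up, at adjusted p = 0.243, 0.337 and 0.243 with an estimated correlation; its median on succinate was -0.06 relative to that of all genes and 0.15 after quantile normalization, when the list was called up on acetate and proline too (adjusted p = 0.0173 and 0.0155). In a fit without the 3 arrays least like their groups, 3 genes of amino acid catabolism rose on glycerol and 12 transport genes on acetate. On succinate, left with 1 array there, fewer genes of amino acid catabolism rose.

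**Figure D3:**
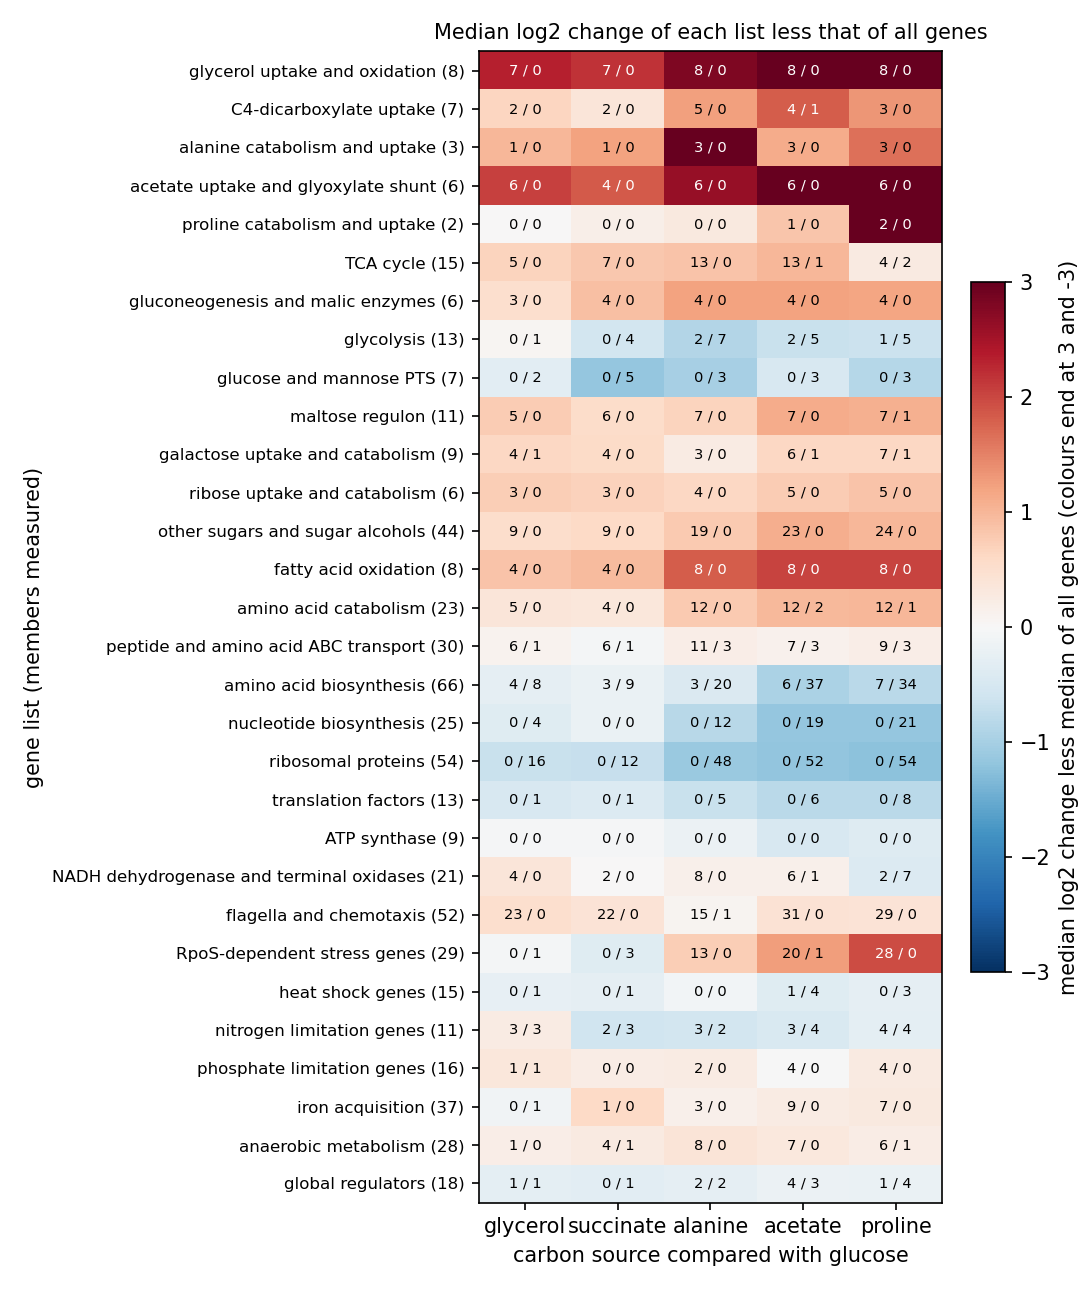
Median log2 change of each gene list less that of all genes (colour), by carbon source compared with glucose; the figures in each cell are the members called higher and lower. The sugar and fatty acid lists are red and the ribosomal, nucleotide and amino acid biosynthesis lists blue on all 5 sources.

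Genes of central carbon metabolism changed in both directions. Of 15 TCA cycle genes 5, 7, 13, 13 and 4 rose (9, 10, 13, 13 and 5 adjusted over the list alone), with the succinate dehydrogenase gene sdhC at 0.94, 1.06, 1.39, 1.48 and 0.40 and the fumarase gene fumA at 0.91, 1.08, 1.10, 1.21 and 1.12. On acetate 1 fell and on proline 2, and there icd, isocitrate dehydrogenase, changed by -0.76 ± 0.16. Camera called the list up on all sources but proline, at adjusted p = 0.123 to 0.585 with an estimated correlation over the 5, and on proline too after quantile normalization (adjusted p = 0.00956), when 7, 7, 14, 14 and 6 rose and 0, 0, 0, 0 and 1 fell. Of 6 gluconeogenesis and malic enzyme genes 3, 4, 4, 4 and 4 rose (3, 5, 6, 4 and 4 adjusted over the list alone), with pck, phosphoenolpyruvate carboxykinase, at 1.62, 1.84, 1.94, 2.22 and 1.90 (camera called up everywhere; adjusted p = 0.0527 to 0.115 with an estimated correlation). Of 13 glycolysis genes 1, 4, 7, 5 and 5 fell (2, 6, 8, 6 and 6 adjusted over the list alone), with the dehydrogenase gene gapA at -0.72, -1.10, -1.34, -1.58 and -1.58. There 0, 0, 2, 2 and 1 rose (2, 1, 2, 2 and 1 adjusted over the list alone), among them the class I aldolase gene fbaB (1.59, 1.72 and 2.20 on alanine, acetate and proline), and with quantile normalization 0, 5, 8, 4 and 6 fell and 0, 0, 2, 1 and 1 rose. Camera called glycolysis down on all sources but glycerol (adjusted p = 0.123 to 0.918 with an estimated correlation over the 5), and on glycerol its median relative to that of all genes was 0.06 while its mean change was -0.10. Of 7 glucose and mannose phosphotransferase genes 2, 5, 3, 3 and 3 fell (3, 7, 6, 3 and 3 adjusted over the list alone), with ptsH at -0.73, -1.12, -1.03, -1.28 and -1.38. Camera called the list down on every source, at adjusted p = 0.173, 0.0428, 0.0919, 0.204 and 0.173 with an estimated correlation. Of 21 NADH dehydrogenase and terminal oxidase genes 4, 2, 8, 6 and 2 rose (9, 2, 8, 6 and 2 adjusted over the list alone) and 0, 0, 0, 1 and 7 fell (0, 0, 0, 2 and 7 adjusted over the list alone). The bd oxidase gene cydA stood at 0.65, 0.74, 1.38, 1.41 and 1.42 and cyoE, of the bo oxidase operon, at -0.99 ± 0.16 on proline. Camera called this list up on glycerol and alanine and down on proline (adjusted p = 0.310, 0.309 and 0.477 with an estimated correlation). After quantile normalization it was called up on acetate too and the call on proline ended (adjusted p = 0.00250 and 0.202). For 9 ATP synthase genes limma called 0, 0, 0, 0 and 0 higher and 0, 0, 0, 0 and 0 lower, with 2, 3, 1, 3 and 3 at an unadjusted p under 0.05 and 0, 2, 0, 0 and 0 higher adjusted over the list alone. Camera called no change (adjusted p = 0.0548 to 0.853), and the medians were -0.03, -0.03, -0.18, -0.48 and -0.40 from that of all genes, or 0.25, 0.19, 0.26, -0.11 and -0.09 after quantile normalization. With that scaling 0, 2, 3, 0 and 0 were higher, and camera called the list up on glycerol, succinate and alanine (adjusted p = 0.0383, 0.00807 and 0.0246). Without the 3 arrays least like their groups 8, 13 and 11 of the NADH dehydrogenase and oxidase genes rose on glycerol, alanine and acetate. On succinate, left with 1 array there, fewer glycolysis and phosphotransferase genes fell and more NADH dehydrogenase and oxidase genes rose.

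In lists of growth and biosynthesis more genes were called lower on alanine, acetate and proline than on glycerol and succinate, where most members were not called. Of 54 ribosomal protein genes 16, 12, 48, 52 and 54 fell (37, 41, 54, 54 and 54 adjusted over the list alone), with rpsT at -1.46, -0.95, -1.83, -2.08 and -2.28, and the median lay -0.67, -0.70, -1.12, -1.17 and -1.24 from that of all genes. Camera called the list down on all 5 sources (adjusted p at most 3.77e-23), and the calls were lost at adjusted p = 0.0898, 0.0769, 0.0536, 0.0641 and 0.0730 with an estimated correlation. After quantile normalization 7, 7, 27, 37 and 43 fell and the medians were -0.15, -0.17, -0.39, -0.61 and -0.62. The brightest probe sets held a larger share of the signal on the 5 glucose arrays than on the other 10, as given above. Without the 3 arrays least like their groups 12, 44, 50 and 49 fell on glycerol, alanine, acetate and proline. Fewer fell on succinate, which that fit leaves with 1 array. Of 13 translation factor genes 1, 1, 5, 6 and 8 fell (4, 4, 6, 8 and 9 adjusted over the list alone), with infA at -1.18, -0.98, -1.48, -1.72 and -1.66 (camera called down everywhere; adjusted p = 0.0527 to 0.10 with an estimated correlation). After quantile normalization the calls on glycerol, succinate and alanine ended (adjusted p = 0.245, 0.220 and 0.0775), 1, 1, 2, 4 and 6 genes fell, and the medians went from -0.49, -0.41, -0.66, -0.80 and -0.81 to -0.03, 0.01, -0.23, -0.19 and -0.22 relative to that of all genes. The genes infC and tufA, at -0.73 and -0.86 on alanine with the deposited scale, stood at 0.08 and 0.02 after it. Of 25 nucleotide biosynthesis genes 4, 0, 12, 19 and 21 fell (7, 0, 16, 20 and 21 adjusted over the list alone, and 4 on succinate at an unadjusted p under 0.05), with carA at -0.84, -0.12, -1.08, -2.54 and -1.85 and pyrB at -0.26, 0.23, -1.04, -2.75 and -1.12. Camera called that list down on all 5, at adjusted p = 0.10, 0.243, 0.0379, 0.0379 and 0.0379 with an estimated correlation, and the call on succinate ended after quantile normalization (adjusted p = 0.0550). Of 66 amino acid biosynthesis genes 8, 9, 20, 37 and 34 fell (15, 14, 22, 44 and 42 adjusted over the list alone) and 4, 3, 3, 6 and 7 rose (5, 6, 3, 7 and 7 adjusted over the list alone). The lysine gene dapB stood at -1.57, -1.32, -1.86, -1.69 and -2.23 and the acetolactate synthase gene ilvB, which rose, at 1.10, 0.75, 1.37, 1.17 and 1.33 (camera called down everywhere; adjusted p = 0.0898 to 0.304 with an estimated correlation). When the 3 arrays least like their groups were left out, fewer amino acid biosynthesis genes fell on succinate, where 1 array remained.

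Of 52 flagella and chemotaxis genes 23, 22, 15, 31 and 29 rose (40, 38, 16, 38 and 32 adjusted over the list alone) and 1 fell on alanine, with the chemoreceptor gene trg at 1.25, 1.08, 1.21, 1.92 and 1.91 and fliZ at 1.09, 1.04, 0.78, 1.21 and 1.39. With quantile normalization 27, 28, 23, 34 and 33 rose and 0, 0, 2, 1 and 1 fell. Camera called the list up on all 5 sources, and each call was lost at adjusted p = 0.0527, 0.0635, 0.441, 0.147 and 0.134 with an estimated correlation. Without the 3 arrays least like their groups 19, 10, 28 and 26 rose on glycerol, alanine, acetate and proline. Fewer rose on succinate, left with 1 array there.

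The RpoS-dependent stress genes set the sources apart. Of 29, 0, 0, 13, 20 and 28 rose (0, 0, 17, 22 and 28 adjusted over the list alone) and 1, 3, 0, 1 and 0 fell (0, 6, 0, 1 and 0 adjusted over the list alone) on glycerol, succinate, alanine, acetate and proline, with 12 and 9 at an unadjusted p under 0.05 on glycerol and succinate. With quantile normalization 0, 0, 8, 19 and 25 rose and 2, 5, 0, 1 and 0 fell. The catalase gene katE stood at 0.66, 0.03, 1.25, 2.07 and 2.65, osmC at 0.48, 0.32, 1.53, 2.50 and 2.63 and the trehalase gene treA at 1.06, 0.89, 2.45, 3.52 and 4.07. Camera called the list up on alanine, acetate and proline and down on succinate, and not on glycerol. The 5 values were adjusted p = 0.774, 0.204, 0.119, 0.0898 and 0.0379 with an estimated correlation. Against the other non-glucose sources 24 of the 29 were higher on proline and 10 on acetate, and 22 were lower on succinate and 12 on glycerol.

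Of 6 further lists camera called 4 on at least 1 source and 2, nitrogen and phosphate limitation, on none. Of 15 heat shock genes 0, 0, 0, 1 and 0 rose and 1, 1, 0, 4 and 3 fell (0, 0, 0, 1 and 0 and 0, 2, 0, 4 and 3 adjusted over the list alone; 3, 4, 3, 5 and 4 at an unadjusted p under 0.05), with the cochaperone gene grpE at -1.03 ± 0.15 on proline. Camera called them down on glycerol and succinate (adjusted p = 0.246 and 0.184 with an estimated correlation), and after quantile normalization 0, 0, 1, 0 and 0 rose, 1, 2, 0, 4 and 4 fell and their medians were -0.15, -0.20, -0.01, 0.05 and 0.05 from that of all genes. Of 11 nitrogen limitation genes 3, 2, 3, 3 and 4 rose and 3, 3, 2, 4 and 4 fell (3, 4, 3, 3 and 4 and 3, 4, 3, 4 and 4 adjusted over the list alone), the glutamine transporter gene glnP at 0.99, 0.67, 1.12, 1.40 and 1.01 and the regulator gene nac at -1.59, -1.74, -1.26, -2.19 and -1.77, with no camera call (adjusted p = 0.0855 to 0.665). Of 16 phosphate limitation genes 1, 0, 2, 4 and 4 rose and 1, 0, 0, 0 and 0 fell (2, 0, 2, 4 and 4 and 1, 0, 0, 0 and 0 adjusted over the list alone; 4, 2, 3, 6 and 5 at an unadjusted p under 0.05). The glycerol 3-phosphate binding protein gene ugpB was at 0.87, 1.57 and 1.46 on alanine, acetate and proline, with no camera call (adjusted p = 0.115 to 0.717), and 1, 0, 1, 3 and 3 rose and 1, 0, 0, 2 and 1 fell after quantile normalization. Of 37 iron acquisition genes 0, 1, 3, 9 and 7 rose and 1, 0, 0, 0 and 0 fell (0, 4, 3, 9 and 7 and 1, 0, 0, 0 and 0 adjusted over the list alone), with sufS, of iron-sulfur cluster assembly, at 2.60 ± 0.57 on proline. Camera called them up on succinate, acetate and proline (adjusted p = 0.218, 0.383 and 0.411 with an estimated correlation), and after quantile normalization 0, 1, 1, 5 and 7 rose, 1, 1, 1, 0 and 1 fell and the call on proline ended (adjusted p = 0.0548). Of 28 anaerobic metabolism genes 1, 4, 8, 7 and 6 rose and 0, 1, 0, 0 and 1 fell (1, 7, 8, 7 and 6 and 0, 3, 0, 0 and 1 adjusted over the list alone), with the fumarate reductase gene frdB at 0.63, 2.14, 1.71, 1.53 and 1.81, and 0, 4, 7, 7 and 6 rose and 0, 2, 2, 1 and 2 fell after quantile normalization. Camera called them up on succinate (adjusted p = 0.184 with an estimated correlation). Of 18 global regulator genes 1, 0, 2, 4 and 1 rose and 1, 1, 2, 3 and 4 fell (2, 1, 2, 4 and 1 and 1, 3, 2, 3 and 4 adjusted over the list alone), with fis, a nucleoid protein gene, at -0.56, -0.39, -1.04, -0.87 and -1.25. Camera called them down on succinate (adjusted p = 0.109 with an estimated correlation). Their medians were -0.29, -0.31, -0.26, -0.17 and -0.20 from that of all genes, and 0.02, -0.04, 0.13, 0.18 and 0.09 after quantile normalization, when 0, 0, 2, 4 and 1 rose, 0, 1, 2, 2 and 2 fell and that call ended (adjusted p = 0.395). Over all lists and sources camera called 75 of 145 tests up and 34 down, and 18 and 4 with an estimated correlation.

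The labels list the 5 sources as glycerol, succinate, alanine, acetate and proline, and a linear slope over that order was fitted for each gene. A called slope does not mean that levels moved the same way at each step, since uraA stood at -0.73 on glycerol and -0.28 on succinate. The slope was steepest upward for bssR (1.49 ± 0.16 log2 per step, adjusted p = 4.57e-05), gadA (1.48 ± 0.17), mcbR (1.33 ± 0.09), gadB (1.32 ± 0.18) and ydcS (1.27 ± 0.20). It was steepest downward for uraA (-0.93 ± 0.06, adjusted p = 9.43e-07), spf (-0.79 ± 0.09), fimB (-0.64 ± 0.12), codB, the cytosine permease (-0.57 ± 0.06), and pppA (-0.54 ± 0.08). Slopes were called upward for 325 genes and downward for 243, together 568. Among the 60 orders of the 5 sources the listed one ranked 2, below 594 genes for the highest, where succinate came before glycerol, with a median count of 75.5 and a lowest count of 2 (exact permutation p = 0.0333, one-sided). Without glycerol replicate 2 the counts were 214 upward and 102 downward. The downward count was 152 without glycerol replicate 1 and 151 and 115 without proline replicates 1 and 2. With arrays centred on the median 258 rose and 301 fell.

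**Figure D4:**
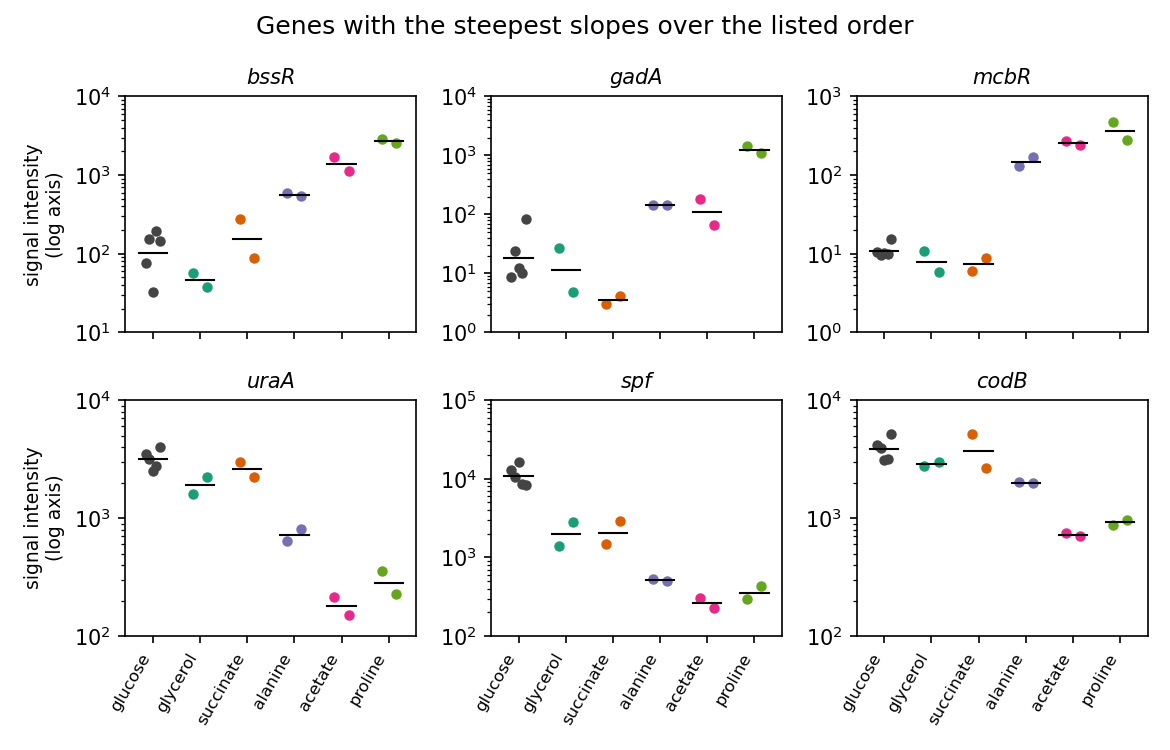
Signal intensity (log axis) on each array of 6 of the genes with the steepest slopes over the listed order, by carbon source; points are arrays and lines geometric means. bssR, gadA and mcbR are highest on proline and lie below the background reference on all 5 glucose arrays, and uraA, spf and codB are lowest on acetate.

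Several of the largest rises started from signals below the background reference on all 5 glucose arrays: 4 of the 8 largest on glycerol, 3 on succinate, 7 on alanine, 8 on acetate and 8 on proline. That reference is high, at 299.4 to 501.6 on the glucose arrays, where the median gene signal was 423.3 to 564.2. The share of all genes below it was not counted, so whether these tallies exceed it is not known. Folds of such rises depend on the floor. With the floor raised from 15.1 to 72.6, alaE on alanine stood at 5.75, curA on glycerol at 1.48, mocA on acetate at 2.57 and on proline at 2.70, mcbR against the other sources on acetate at 0.97 and gadA over the listed order at 0.89, all still called. The same floor gave fimB -1.86 and yhcN -1.69 on proline, and fimB 0.93 on succinate against the other sources and -0.24 over the listed order, and mcbR 0.65 over that order, again called. It ended the calls of amtB on glycerol and succinate (adjusted p = 0.0837 and 0.0899), csgE on succinate and on alanine against the other sources (0.635 and 0.123), yjfZ on glycerol (0.192) and yhjY on acetate (0.0674).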

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

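The tests on the control probe set below were chosen after the result was seen, except for the search for another transcript.

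The Affymetrix control probe set AFFX-BioC-3, which is outside the comparisons of genes, was brighter on every other source than on glucose. Its log2 changes were 2.0, 2.28, 2.85, 3.36 and 3.34 (SE 0.77) on glycerol, succinate, alanine, acetate and proline. The probe set for the cell's own bioC gene changed by -0.17 on proline, where 1.67 is 0.5 of the rise, which argues against the cell's bioC RNA as the whole of the rise. The control AFFX-BioB-5 changed by 0.11 on proline, also below 1.67. Its changes (0.05, 0.34, 0.41, 0.15 and 0.11) lay near those of the cell's own bioB gene (0.04, 0.42, 0.46, 0.27 and 0.18). Whether AFFX-BioB-5 reads added control or the cell's bioB RNA is not known, so it cannot decide whether more control was added. Binding of another transcript that changes with the source cannot be told apart from other origins. Over the 15 arrays 48 gene probe sets correlated above 0.9 with AFFX-BioC-3, as genes that follow the source do. Apart from the cell's own bioC RNA, no biological explanation was tested.

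Among 2886 intergenic probe sets, which the comparisons of genes do not use, 48, 32, 171, 207 and 292 were called higher on glycerol, succinate, alanine, acetate and proline than on glucose, and 28, 19, 103, 171 and 148 lower. Of 59 phage and plasmid probe sets limma called 0 higher on any source, and 0, 0, 0, 1 and 1 lower, with 2, 5, 4, 4 and 6 at an unadjusted p under 0.05 in either direction.

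In 9 of 116 sets of 5 glucose values Dixon's ratio flagged a single array as apart from the other 4, where chance gives 5.80. The ratio was taken on log2 values after the floor of 15.1, while the signals given here are those before it. On glucose replicate 5, which also had the lowest mean correlation with its group, the signal was 77.7 for curA (median of the 5 arrays 19.4), 114.3 for dcuD (30.9), 84.5 for gadA (12.4), 302.1 for yhjY (77.2), 15.5 for mcbR (10.2) and 2214.7 for cyoE (2785.3). On glucose replicate 1 it was 51.7 for tnaA (178.5), on replicate 2 190.4 for tnaC (115.1) and on replicate 3 21.1 for mocA (12.6). All but cyoE lay below the background reference of the array. For mcbR the other 4 signals (9.6 to 10.6) were all raised to the floor, so its flag comes from the floor and not from a distant value. For gadA the signals 8.8, 10 and 12.4 became equal in the same way, and for mocA the median lay below the floor. The test was not repeated without the floor.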

How the results depend on the processing

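Apart from the fit without the 3 arrays least like their groups, which was added after the data were seen, all alternatives were planned. Counts below are of higher and lower genes, and the cause of a change was not tested unless it is given.

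Of 18040 pairs of a gene result and an alternative, 16934 kept direction and side of the threshold, 1064 lost the call, 40 gained one and 2 reversed. Results called in neither fit count as kept. Many pairs come from fits without 1 array of a group outside the comparison, which can change little. The sizes of changes are not counted there, and with the floor of 72.6 curA on glycerol went from 3.02 to 1.48 and csgE on succinate from -2.38 to -0.34. The 2 that reversed were infC (0.082) and tufA (0.0245) on alanine after quantile normalization. No gene was called in opposite directions with the deposited scale and after quantile normalization, and 275, 254, 633, 952 and 1074 calls were shared on glycerol, succinate, alanine, acetate and proline.

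With arrays centred on the median the counts against glucose were 132 higher on glycerol, 118 higher on succinate, 318 and 508 on alanine, 460 and 722 on acetate, and 471 and 864 on proline. Against the other sources they were 64 lower on glycerol, 114 lower on succinate, 17 higher on alanine, and 41 and 14 on acetate, and 82 genes were higher on all 5. After quantile normalization 205 were lower on proline and 100 higher on succinate than on the other sources. The share of higher genes among those called on proline went from 56.1% to 44.4% and 35.3% with quantile normalization and median centring.

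A minimum of 2-fold, which adds a condition, left 127 and 37 on glycerol, 122 and 30 on succinate, and 158, 211 and 281 lower on alanine, acetate and proline. Against the other sources it left 14 higher on glycerol, 14 higher on succinate, 53 and 12 on acetate and 34 lower on proline. It left 84 and 10 on all 5 sources. For slopes the minimum was 2-fold per step, which is stricter than 2-fold between groups. It left 14 upward and 0 downward slopes in limma, of 1032 at an unadjusted p under 0.05, where the steepest downward slope was -0.93 per step.

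With the replicate number as a block 129 genes were higher on acetate than on the other sources, 63 lower on glycerol and 54 lower on succinate than on glucose, and 25 lower on all 5. Whether the numbers pair the arrays is not settled: correlations of deviations ran from -0.26 to 0.28, 9 of 30 were over 0.1, and 8 of 12 arrays were closer to their own number. With no variance trend 16 were lower on acetate, 69 lower on proline, 23 higher on glycerol and 30 higher on succinate than on the other sources, and 29 lower on all 5. With the arrays of the compared groups alone, which are fewer, the counts were 121 and 56 on glycerol, 78 and 29 on succinate, and 60 and 15 on all 5. Without the 3 arrays least like their groups 41 were lower on succinate and 27 lower on all 5, and against the other sources 141 and 61 changed on acetate, 177 were lower on glycerol, 207 lower on proline and 112 lower on succinate. With an estimated correlation camera called 18 list shifts up and 4 down, against 75 and 34 of 145 with the preset one.

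Leaving out single arrays, where a lone array is assumed to vary like the other groups, gave ranges against glucose of 86 to 243 and 24 to 141 on glycerol, 119 to 222 and 39 to 124 on succinate, 275 to 602 and 119 to 328 on alanine, 412 to 774 and 236 to 475 on acetate, and 404 to 776 and 342 to 582 on proline. Against the other sources they were 3 to 56 and 16 to 146 on glycerol, 22 to 65 and 63 to 201 on succinate, 9 to 34 and 3 to 15 on alanine, 6 to 120 and 6 to 44 on acetate, and 38 to 164 and 16 to 163 on proline. They were 75 to 147 and 9 to 60 for all 5 sources, 214 to 360 and 102 to 276 for the listed order, and 893 to 1151 for any difference. Signal over background limits folds of dim genes, as given with the floor of 72.6.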

Other observations

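Neighbouring genes by b number, examined after their values were seen, changed together more often than apart when a source was compared with the other 4. Unequal numbers of higher and lower genes alone favour the same direction, and the tallies were not set against chance. Among 4295 adjacent pairs both genes were called in the same direction in 23, 46, 12, 17 and 54 pairs on glycerol, succinate, alanine, acetate and proline, and in opposite directions in 2, 3, 2, 1 and 7. On alanine stpA, a nucleoid protein gene, stood at -2.76 and its neighbour alaE, the alanine exporter gene, at 5.89. On succinate eco stood at -0.75 and its neighbour mqo at 2.14. The strands and promoters of these pairs were not examined.

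The tests of array scaling, of bright probe sets on sources other than proline, of slower growth, of the arrays least like their groups, of lists over the listed order and of the share of catabolic lists were chosen after the result was seen.

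Of 54 ribosomal protein genes 16, 12, 48, 52 and 54 were called lower on glycerol, succinate, alanine, acetate and proline (7, 7, 27, 37 and 43 after quantile normalization). Camera called the list down on all 5, and each call was lost at adjusted p = 0.0536 to 0.0898 with an estimated correlation. Their median less that of all genes was -0.15, -0.17, -0.39, -0.61 and -0.62 after quantile normalization, and with the deposited scale, relative to genes matched on mean signal, which changed by -0.31, -0.32, -0.40, -0.50 and -0.44, it was -0.29, -0.28, -0.49, -0.51 and -0.66. On acetate and proline both stayed below -0.3 by more than their spread (SE 0.0621 and 0.0643, and upper limits of 95% of 1000 draws -0.303 and -0.514). That spread is between genes, taken as independent, and leaves out the variation between arrays. The fall thus remained there after either step, but array scaling and a lower response of bright probe sets are not excluded. On glycerol and succinate the values went with either, and on alanine neither is settled. Slower growth on the poorer sources may account for the fall (-1.24 on proline with the deposited scale), but growth rates were not given, so this stays open.

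More genes were called on alanine, acetate and proline (858, 1175 and 1271) than on glycerol and succinate (333 and 296). Succinate, later in the listed order, had fewer than glycerol, and without glycerol replicate 1 or 2 it had more (241 each time against 110 and 137). The ratio of genes called on proline to those on glycerol was 3.82 with the deposited scale and 3.50 without the 3 arrays least like their groups. Those 3 are glucose and succinate arrays, so leaving them out could hardly change this ratio and decides nothing about it. The ratio was 3.96 after quantile normalization and 5.11 with arrays centred on the median, which argues against array scaling as the whole cause of a ratio over 1.5. Its size depended on single arrays, with 11.1 and 8.89 without glycerol replicates 1 and 2, 2.66 and 2.77 without proline replicates 1 and 2, and 5.68 with the arrays of the compared groups alone. A difference between the sources themselves may lie behind the ratio, and this was not tested.

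The number of genes that differed among the 6 sources was set against regroupings of the 15 arrays into groups of the same sizes. Of 100 groupings 1, the real one, gave 1073 genes or more, and the highest other gave 846. A random grouping of the arrays thus seldom gives as many genes. The regroupings cannot tell the carbon source from anything else that the arrays of a group share, such as a common culture.

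Lists were tested over the listed order with camera on the slopes. At the preset correlation 8 of 29 were called up and 7 down, and 3 and 1 with an estimated correlation. The 3 were the RpoS-dependent stress genes (29 of 29 slopes called upward, adjusted p = 0.0109), the acetate and glyoxylate genes and fatty acid oxidation (0.0311 each). The 1 was nucleotide biosynthesis (adjusted p = 0.0240). For most of the 8 lists a shift that follows the listed order is thus not settled. The 132 genes higher on all 5 sources held 39 of the 127 members of the 11 catabolic and uptake lists, 29.5% of these genes against 2.92% of all genes (Fisher's exact test, one-sided, p = 1.81e-30, genes taken as independent). Another 65 of them were in no list. A common rise concentrated in those lists is a candidate explanation, found and tested on the same data.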
